A study of Arabidopsis thaliana with 12 samples.

How the data were processed

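RNA sequencing libraries came from roots of Arabidopsis thaliana plants that carry 35S:XVE>>PLT5-TagRFP, a construct in which the estradiol-activated regulator XVE drives PLT5 fused to the red fluorescent protein TagRFP. Per the labels, plants were treated with the solvent DMSO (mock) or with estradiol (induced) for 8 h or 24 h, with 3 biological replicates in each of the 4 groups. Each of the 12 samples pooled 1.5 cm root segments, taken below the junction of root and hypocotyl, from 15 plants, and visible lateral roots were removed. Total RNA was isolated with a GeneJET Plant RNA kit and libraries were made with a TruSeq Stranded Total RNA kit, per the labels' protocols. The aligner, the counting program and its strand setting are not given in the sources used here. Per the file headers, each deposited file holds 1 column of gene counts with the locus identifier, chromosome, start, end, length and strand, and the genome build is TAIR10, per the submitters' processing notes.

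The values were whole numbers for 34262 loci in every file, and no locus was a summary of unassigned reads. Library totals lay between 34958324 and 41447647 counts. Where a gene had 0 counts in the 3 libraries of a group, bounds on fold changes assumed 3 counts over that group. Ratios for groups with 1 to 3 counts carry 95% counting intervals. Intervals and floors cover counting error only. Locus identifiers were matched to the RefSeq TAIR10.1 annotation by locus tag for 32548 loci, of which 99.95% had the same start and end after conversion of the 0-based starts in the files. Gene symbols were taken from that annotation and, for list members, from the lists fixed with their AGI codes. Among 293 genes nested inside and antisense to a gene with a mean of at least 2000 counts, the median of the mean counts was 0.42. The median for the outer genes was 3229, and 63.8% of the nested genes lay under 1 count. Reads of the outer genes were thus rarely counted for the nested genes. This cannot decide whether counting was by strand, since dropping reads that overlap more than 1 gene would also leave nested genes near 0. Genes with near-identical copies can share reads, and only some of the named genes with such copies are marked as uncertain. PLT5 counts pool the native gene and the transgene, since the files hold no separate entry for the construct.

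Differential expression was tested in R 4.3.3 with the quasi-likelihood F test of edgeR 4.0.16 on the deposited counts, with TMM scaling, filterByExpr by group and a means model with 1 coefficient per group over all 12 libraries. The filter left 21439 genes. The contrasts were induced against mock at 8 h, induced against mock at 24 h, the difference of these responses (the interaction, 24 h minus 8 h) and mock at 24 h against mock at 8 h. P-values were adjusted by the Benjamini-Hochberg method and called at 0.05. Adjusted p-values of genes come from edgeR throughout unless DESeq2 is named. The standard error (SE) of a log2 fold change was its absolute value divided by the square root of F. Counts-per-million values (CPM) use TMM-scaled library sizes and are given as mean ± SD of 3 libraries.

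Lists of genes, 28 in number with 399 distinct genes, were written with the tests before the data were examined, as were the rule for named genes and most alternatives. They covered the PLT/AIL family, cambium regulators, HD-ZIP III genes, xylem differentiation, lignin biosynthesis, phloem, suberin and cork, auxin biosynthesis, auxin transport, auxin early response, cytokinin response and metabolism, gibberellin metabolism and perception, S phase and DNA replication, mitosis and cytokinesis, D-type cyclins and CDK inhibitors, lateral root founding and organ boundaries, embryonic and shoot regeneration regulators, cell wall loosening, jasmonate and wound response, salicylate and pattern-triggered defence, circadian clock, root hair and epidermis, endodermis and Casparian strip, cortex, root tip meristem and root cap, pericycle, photosynthesis (green tissue) and housekeeping. CYCD3;1, LBD16, LBD18, LBD29 and LBD33 sit in more than 1 list. PLT5 was left out of list tests. The 26 lists with at least 3 tested members were tested with camera of limma 3.58.1 with the preset inter-gene correlation of 0.01, adjusted over lists. Camera asks whether a list moved differently from the other genes. It was repeated with a correlation estimated from each list. The rotation test fry was the other alternative: its PValue asks whether the genes of a list move on balance in 1 direction and its PValue.Mixed whether they change in either direction, and neither compares a list with other genes. Cortex and pericycle, with 2 members each, were not tested as lists.

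The text names PLT5, the 5 largest rises and 5 largest falls per induction contrast among called genes with at least 5 CPM in the higher group and no overlap of CPM between groups, up to 4 called members per list in order of adjusted p, and members of the PLT/AIL and cambium lists whether called or not. For the interaction and the mock contrast it names the 4 largest rises and 4 largest falls among called genes with at least 5 CPM in the highest group. In the mock contrast CPM of the groups also had to be without overlap. Up to 4 called members of any list are named too. Genes named outside this rule are stated as such, apart from a few members given to complete a list.

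Samples of the same replicate number were checked for pairing by the correlation of their deviations from the group means over 14137 genes with a mean above 3 log2 CPM. At 24 h the correlations were 0.31, 0.22 and 0.35 for replicates 1, 2 and 3, above 0.1 for each pair. The alternative fit with a replicate block treated libraries of the same number as paired over all 4 groups. The 8 h libraries and the mock times did not meet this criterion. The labels do not say what a number stands for.

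Alternatives were DESeq2 1.42.0, RLE factors, total library size alone, no low-count filter, a filter of 5 CPM in 3 libraries, a fit of the 6 libraries compared, the replicate block, removal of organelle and ribosomal RNA loci, an absolute log2 fold change of at least 1, and leaving out each library in turn. Each statistical step was tested on simulated counts drawn from the means and library sizes of the real samples. With edgeR, changed genes at folds of 1.5, 2 and 4 were recovered at 53.7%, 86.6% and 93.9% for the 8 h contrast and at 56.9%, 77.6% and 93.8% for the 24 h contrast. For the interaction these shares were 31.3%, 78.8% and 96.9%, and for the mock contrast 70.1%, 86.4% and 98.5%. Of 21002, 20992, 20985 and 21005 unchanged genes, 7, 2, 9 and 9 were called in these contrasts. In each contrast camera recovered a shifted list of 20 genes, with an estimated correlation too, and gave no unshifted list an unadjusted p under 0.05. The simulated genes varied independently, whereas estimated correlations within real lists reached 0.67 (HD-ZIP III genes). Far fewer genes changed in the simulations than in the real contrasts. They therefore do not show how often camera with the preset correlation calls correlated lists falsely. Nothing was left out of the deposited libraries, and no plants without the construct were part of the series, so effects of estradiol itself cannot be separated from those of PLT5.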

Results

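Gene counts were measured by RNA sequencing in root segments of Arabidopsis plants in which estradiol switches on the transcription factor PLT5. The 12 libraries formed 4 groups of 3 biological replicates: mock and induced roots at 8 h and mock and induced roots at 24 h. Total counts per library ranged from 34958324 in mock 8 h replicate 2 to 41447647 in mock 24 h replicate 2. Replicates of a group correlated at 0.989 to 0.9932 on log2 CPM across genes, which are not independent replicates, and the biological coefficient of variation was 0.093. Each fold change below compares 3 induced with 3 mock libraries unless stated otherwise, and rose, fell and changed are used for genes with an edgeR adjusted p under 0.05.

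PLT5 itself (AT5G57390, chromosome 5, 23252989 to 23256703, minus strand, TAIR10) followed the labels in all 12 libraries. Its level was 13.27 ± 1.49 CPM (SD, n = 3) in mock and 2467 ± 143 CPM in induced roots at 8 h, and 14.11 ± 2.78 CPM in mock and 2795 ± 123 CPM in induced roots at 24 h. The log2 fold change was 7.54 at 8 h (SE 0.147, adjusted p = 2.9e-11) and 7.63 at 24 h (SE 0.147, adjusted p = 7.44e-12). Its responses at the 2 times were not called different (adjusted p = 0.695). In the 6 induced libraries PLT5 ranked between 14 and 19 among all genes by count.

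**Figure D1:**
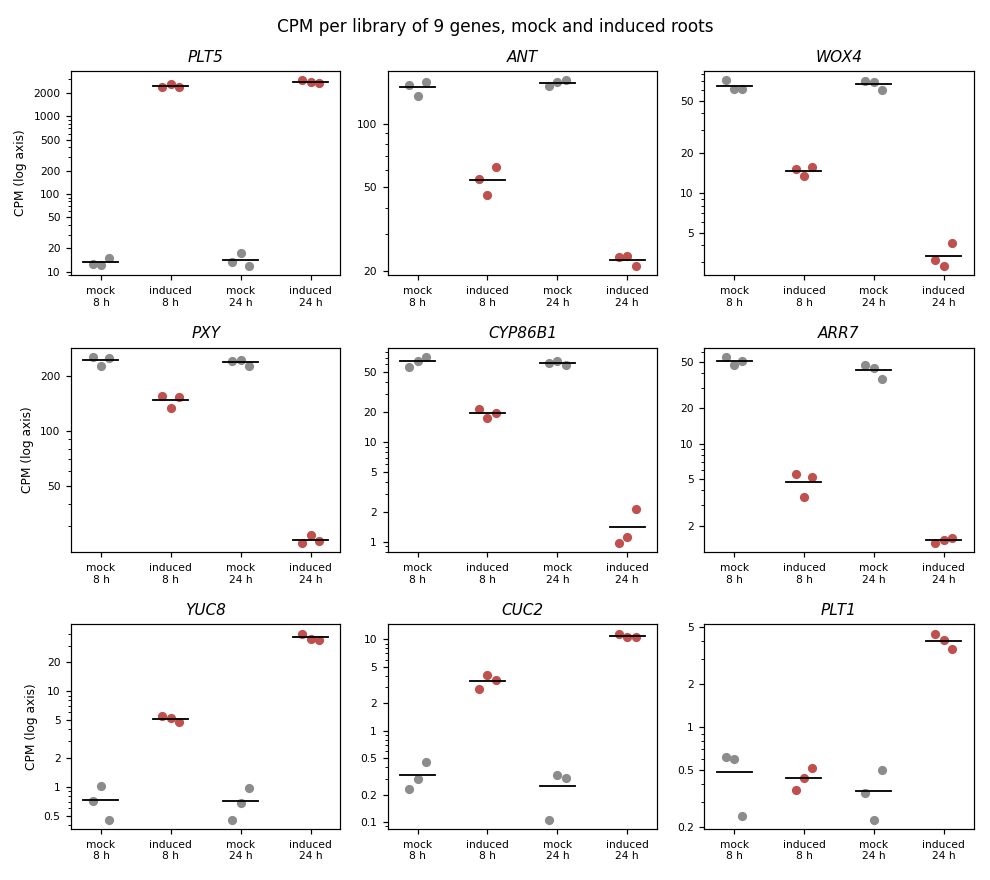
CPM per library on log axes for 9 genes, with grey points for mock and red points for induced libraries and a bar at the mean of 3 libraries. PLT5 lies near 2467 and 2795 CPM in induced roots, WOX4, PXY, ANT, CYP86B1 and ARR7 step down from mock to 8 h to 24 h, YUC8 and CUC2 step up, and PLT1 is higher in the 3 induced 24 h libraries only among the groups plotted.

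The first principal component of 14137 genes held 84.5% of the variance and the second 8.8%. Mock libraries lay between -41.1 and -34.5 on the first component, induced 8 h libraries between -1.1 and 7.0, and induced 24 h libraries between 69.9 and 79.7. The second component set the induced 8 h libraries, at -29.1 to -19.3, apart from the other 9 libraries.

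**Figure D2:**
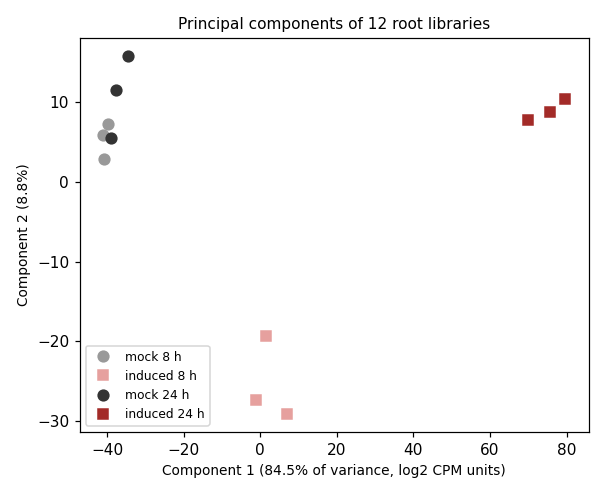
Position of the 12 libraries on the first and second principal components of log2 CPM, with circles for mock and squares for induced roots. Induced 24 h libraries lie between 69.9 and 79.7 on the first component, and the mock libraries of both times lie together at -41.1 to -34.5.

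The 8 h comparison asks which genes responded early to induction. Most cambium regulators (18 of 29), cytokinin genes (23 of 28) and cell wall loosening genes (8 of 9) fell within 8 h, and these list calls held with an estimated correlation. Of 23 suberin and cork genes 19 fell, in a list whose call was lost with an estimated correlation (adjusted p = 0.331). The auxin biosynthesis genes YUC8, YUC9 and TAA1 and the boundary gene CUC2 rose from low levels, while 3 of 9 auxin biosynthesis genes fell, YUC6 among them, and that list's call was lost with an estimated correlation (adjusted p = 0.394). The cambium gene WOX4 (AT1G46480) fell from 64.6 ± 6.05 to 14.77 ± 1.25 CPM, and the cytokinin response gene ARR7 (AT1G19050) fell from 50.68 ± 4.25 to 4.752 ± 1.1 CPM. The auxin biosynthesis gene YUC9 (AT1G04180) rose from 3.677 ± 0.585 to 26.96 ± 1.2 CPM, and the boundary gene CUC2 (AT5G53950) rose from 0.3272 ± 0.113 to 3.524 ± 0.625 CPM. Of 21439 genes tested, 9748 changed, with 4785 higher and 4963 lower, and 2085 of them had an absolute log2 fold change of at least 1 (478 higher and 1607 lower). The share of higher genes among those called was 49.1% with TMM, 43.8% with RLE factors and 65.1% with total library size alone, which moved the median of all genes by 0.096 at 8 h and 0.142 at 24 h. Without overlap of the 3 induced and 3 mock CPM values were 11808 genes, or 55.1%, against 10% by chance.

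In the PLT/AIL family at 8 h, ANT (AT4G37750) fell by 1.46 on the log2 scale (SE 0.096, adjusted p = 3.28e-07) and PLT3 (AT5G10510) fell by 1.08 (SE 0.1, adjusted p = 4.41e-06). PLT1, PLT2, BBM and PLT7 were not called, with log2 fold changes of -0.13, -0.33, 0.37 and 0.07. The list of 6 tested genes other than PLT5 had 2 that fell, also when adjusted over the list alone, and was not called (camera, adjusted p = 0.0631). It was called without mock 8 h replicate 3 (0.0471), without induced 8 h replicate 2 (0.0339), without induced 8 h replicate 3 (0.0209) and with total library size (0.047).

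Of 29 tested cambium regulators, 4 rose and 18 fell at 8 h, against 4 and 20 adjusted over the list alone. The median log2 fold change was -0.57, and the list was called lower (camera, adjusted p = 3.89e-07, and adjusted p = 0.0348 with an estimated correlation). PTL fell by 2.51 (SE 0.124, adjusted p = 6.61e-08), WOX4 by 2.13 (SE 0.115, adjusted p = 8.42e-08) and LBD4 by 1.70 (SE 0.09, adjusted p = 8.29e-08). LBD3, LBD1, HAM4 and PXL1 had log2 fold changes of -2.51, -1.37, -1.30 and -1.14, and CLE41, RUL1, WOX14, PEAR1, PXY, KNAT1, SMXL4, SMXL5, HAM3 and CYCD3;1 fell by less, and CYCD3;1 was not called with total library size (0.0727, range 0.000938 to 0.0727). PXY (AT5G61480) was 243.1 ± 15.7 CPM in mock and 147.4 ± 12.2 CPM in induced roots. PXL2 fell (adjusted p = 0.0225, range over alternatives 0.00466 to 0.0847), but not without mock 8 h replicate 1 (0.0505) or 2 (0.0723) or induced 8 h replicate 1 (0.0522) or 2 (0.0847). HAM2 rose (adjusted p = 0.0369, range 0.00625 to 0.183), but not without mock 8 h replicate 1 (0.0552), 2 (0.12) or 3 (0.0593) or induced 8 h replicate 1 (0.183) or 2 (0.0545), nor with DESeq2 (0.0568) or RLE factors (0.0614). SMXL3 rose by 1.67 on the log2 scale (SE 0.103, adjusted p = 2.07e-07), and LBD11 and HAM1 rose by 0.52 and 0.51. CLE44, CLE42, MOL1, TMO6, PEAR2, MYB87 and ARF5 were not called, though CLE42 (adjusted p = 0.0531, range 0.0187 to 0.288) was with DESeq2 (0.0374), with RLE factors (0.0427) and without mock 8 h replicate 1 (0.0187) or 2 (0.0481) or induced 8 h replicate 2 (0.0453). MYB87 was called with the replicate block (0.0331) and total library size (0.0404), CLE44 with the 6-library fit (0.00618) and DESeq2 (0.0392), and PEAR2 and ARF5 with total library size (0.0257 and 0.0249). Ranges over alternatives were 0.0331 to 0.374 for MYB87, 0.00618 to 0.221 for CLE44, 0.0257 to 0.332 for PEAR2 and 0.0249 to 0.976 for ARF5.

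Among cell type lists at 8 h, 19 of 23 suberin and cork genes fell and 1 rose, against 20 and 1 adjusted over the list alone (median -0.90; camera, adjusted p = 3.61e-07, and adjusted p = 0.331 with an estimated correlation). MYB9 fell by 2.20, ABCG20 by 1.58 and CYP86B1 (AT5G23190) by 1.72 (SE 0.149, adjusted p = 2.54e-06), whereas MYB84, named after its values were seen, rose by 0.72 on the log2 scale. Of 17 phloem genes 10 fell and 2 rose, 11 and 2 adjusted over the list alone (median -0.78; adjusted p = 0.00809, and adjusted p = 0.44 with an estimated correlation). OPS fell by 0.78 and CLE45 by 2.28, whereas the sucrose transporter gene SUC2 (AT1G22710) rose from 34.63 ± 5.16 to 179.6 ± 19.7 CPM (log2 fold change 2.38, SE 0.161, adjusted p = 4.03e-07). Of 15 lignin genes 13 fell and 1 rose, with the same counts adjusted over the list alone (median -0.63; adjusted p = 3.32e-05, and adjusted p = 0.247 with an estimated correlation). PAL1 and PAL2 fell by 1.25 and 1.31, and FAH1 rose by 1.97 on the log2 scale. Of 28 xylem genes 8 fell and 1 rose, 7 and 1 adjusted over the list alone, with a median of -0.25, and the list was not called (adjusted p = 0.206). The cortex genes PEP and CO2 fell by 3.31 and 1.04, though CO2 was not called by DESeq2 (adjusted p = 0.0563, range over alternatives 0.00248 to 0.0563). The pericycle gene PHO1 fell from 138.9 ± 14.9 to 55.83 ± 2.44 CPM. SKOR was called lower (adjusted p = 0.0259, range 0.00858 to 0.0997), but not without mock 8 h replicate 2 (0.0997) or 3 (0.0643) or induced 8 h replicate 1 (0.0685), 2 (0.0513) or 3 (0.0689). The cortex and pericycle lists, with 2 genes each, had the same counts adjusted over the list alone and were not tested as lists.

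Hormone lists at 8 h moved in different directions. Of 28 cytokinin genes 23 fell and 4 rose, with the same counts adjusted over the list alone (median -1.23; adjusted p = 5.47e-08, and adjusted p = 0.0261 with an estimated correlation). ARR7 fell by 3.41 (SE 0.151, adjusted p = 4e-08), ARR5 by 2.39 and CKX5 by 2.58, while CKX7 rose by 1.46 on the log2 scale. Of 9 auxin biosynthesis genes 3 rose and 3 fell, 4 and 3 adjusted over the list alone. YUC9, YUC8 and TAA1 had log2 fold changes of 2.88 (SE 0.158), 2.83 (SE 0.218) and 2.69 (SE 0.222), and YUC6 fell by 1.58. This list was called higher (adjusted p = 0.0321, and adjusted p = 0.394 with an estimated correlation) with a mean of 0.61 but a median of -0.05, which was 0.04 with total library size. The call was lost without mock 8 h replicate 1 (0.0527), without mock 8 h replicate 3 (0.0706), with total library size (0.0732) and with the replicate block that pairs libraries by number (0.0753). Auxin early response genes included 9 of 22 that rose and 3 that fell, with the same counts adjusted over the list alone (median 0.21; adjusted p = 0.00809, and adjusted p = 0.247 with an estimated correlation), among them HAT2, IAA4 and LBD33 at 1.99, 1.25 and 3.12. Auxin transport genes included 7 of 14 that fell and 2 that rose, with the same counts adjusted over the list alone (median -0.21; adjusted p = 0.00186, and adjusted p = 0.247 with an estimated correlation). PIN7 fell by 1.62, PIN5 by 2.52 and LAX3 by 1.60. Of 14 gibberellin genes 2 rose and 4 fell, with the same counts adjusted over the list alone, and GA20OX2 rose from 0.3705 ± 0.202 to 5.052 ± 0.673 CPM. That list was not called (adjusted p = 0.842), and the direction of its test (up) differed from its median of -0.16 and mean of -0.14.

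Other lists called at 8 h were cell wall loosening, lateral root founding and organ boundaries, and the circadian clock. Of 9 cell wall loosening genes 8 fell and none rose, also adjusted over the list alone (median -1.71; adjusted p = 5.47e-08, and adjusted p = 0.0345 with an estimated correlation), with EXPA15 and EXPA10 at -2.44 and -2.12. Of 12 lateral root and boundary genes 7 rose, and 7 rose and 1 fell adjusted over the list alone (median 0.32; adjusted p = 0.00142, and adjusted p = 0.0348 with an estimated correlation). CUC2, LBD33 and WOX11 had log2 fold changes of 3.42 (SE 0.265), 3.12 (SE 0.3) and 2.86 (SE 0.296). Of 19 clock genes 10 rose, also adjusted over the list alone (median 0.28; adjusted p = 0.00842, and adjusted p = 0.38 with an estimated correlation), led by RVE1 at 2.39.

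Cell cycle lists were not called at 8 h. Of 15 S phase genes 7 rose, also adjusted over the list alone (median 0.20, adjusted p = 0.055), and E2FA rose from 7.7 ± 0.815 to 15.66 ± 1.22 CPM. The S phase list was called without mock 8 h replicate 1 (0.0124), without mock 8 h replicate 3 (0.041), without induced 8 h replicate 1 (0.0244) and with total library size (0.047). Of 23 mitosis genes 8 fell and 1 rose, also adjusted over the list alone (median -0.20, adjusted p = 0.146). Of 13 D-type cyclin and CDK inhibitor genes 6 fell and 2 rose, also adjusted over the list alone (median -0.26, adjusted p = 0.0964), with SIM at -2.29.

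The remaining lists were not called at 8 h, and counts adjusted over the list alone were the same unless given. HD-ZIP III genes included 1 that rose and 2 that fell, 1 and 3 adjusted over the list alone (adjusted p = 0.691). In the embryonic list AGL15 fell by 0.61 and 3 others were not called (adjusted p = 0.633). Jasmonate genes included 1 of 17 that fell (adjusted p = 0.752), and salicylate and defence genes 2 that rose and 2 that fell (adjusted p = 0.597), with PAD3 at -3.74. Root hair genes included 1 that rose (adjusted p = 0.948), with a median of -1.11 and a mean of -0.61 against a test direction of up. Endodermis genes included 1 that rose and 4 that fell, 1 and 6 adjusted over the list alone (median -1.17, adjusted p = 0.338). SHR and WOX5 of the root tip list rose (adjusted p = 0.123 for the list), and photosynthesis genes included 3 that rose and 1 that fell (adjusted p = 0.232). Of 7 housekeeping genes ACT7 and ACT2 fell by 0.39 and 0.32 (adjusted p = 0.484 for the list).

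Apart from PLT5 itself, the largest rises at 8 h were in AT1G15330, encoding a CBS domain protein, and in the malate synthase gene MLS. AT1G15330 had 612 counts against 3 in mock (ratio 187, counting interval 64.6 to 922). MLS rose from 1.337 ± 0.31 to 49.75 ± 2.31 CPM (log2 fold change 5.22, SE 0.115, adjusted p = 6.35e-11). The neighbouring receptor-like kinase related genes AT5G41290 and AT5G41300 rose by 4.75 and 4.42 on the log2 scale, and reads could not be assigned with certainty between these similar copies. The largest falls were in AT5G57785 (-5.93), the acyltransferase gene PMAT2 (-5.81), AT4G25433 (-5.11), AT2G44940 (-4.95) and AT3G46880 (-4.91), with SEs of 0.317, 0.355, 0.328, 0.199 and 0.297. AT2G44940, which encodes an integrase-type DNA-binding protein, fell from 116.3 ± 13.4 to 3.745 ± 0.918 CPM.

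The 24 h comparison asks how far the response had gone a day after induction. Most cambium regulators (25 of 29) and both cortex genes fell, and PLT1 and BBM rose. Most suberin (22 of 23), xylem (27 of 28) and phloem genes (14 of 17) fell, and most S phase (13 of 15), mitosis (18 of 23) and root tip genes (3 of 4) rose. These 6 list calls were lost with an estimated correlation (adjusted p = 0.104, 0.436, 0.212, 0.436, 0.618 and 0.183 in that order). WOX4 fell from 66.41 ± 5.42 to 3.35 ± 0.717 CPM. The suberin gene CYP86A1 (AT5G58860), named outside the rule for this contrast, fell from 340.9 ± 27.1 to 13.46 ± 5.09 CPM. YUC8 rose from 0.701 ± 0.262 to 36.58 ± 2.85 CPM, and PLT1 (AT3G20840) rose from 0.3575 ± 0.139 to 4.0 ± 0.498 CPM. Of 21439 genes, 15505 changed, with 8216 higher and 7289 lower, and 5185 had an absolute log2 fold change of at least 1 (1250 higher and 3935 lower). The share of higher genes among those called was 53.0% with TMM, 49.5% with RLE factors and 62.9% with total library size. Without overlap of CPM between the groups were 16159 genes, or 75.4%, against 10% by chance.

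In the PLT/AIL family at 24 h, ANT fell by 2.79 (SE 0.102, adjusted p = 2.98e-10), PLT3 by 1.44 (SE 0.102, adjusted p = 7.1e-08) and PLT7 by 0.94 (SE 0.111, adjusted p = 7.32e-06). PLT1 rose by 3.48 on the log2 scale (SE 0.312, adjusted p = 6.38e-07) and BBM rose from 0.2562 ± 0.0341 to 2.382 ± 0.373 CPM (adjusted p = 1.77e-05). PLT2 rose by 1.65 (SE 0.558, adjusted p = 0.0179), from 0.2712 ± 0.186 to 0.8455 ± 0.207 CPM, but not without mock 24 h replicate 2 (0.0709) or induced 24 h replicate 3 (0.057), with a range of 0.0104 to 0.0709 over alternatives. Of the 6 genes 3 rose and 3 fell, also adjusted over the list alone. The list was not called (camera, adjusted p = 0.401), and its test direction was down against a median of 0.35 and a mean of 0.53.

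All 29 tested cambium regulators changed at 24 h, with 25 lower and 4 higher, also adjusted over the list alone. The median was -1.53 (camera, adjusted p = 2.06e-11, and adjusted p = 0.0302 with an estimated correlation). LBD3 fell by 5.12 (SE 0.253), WOX4 by 4.31 (SE 0.133), LBD4 by 3.70 (SE 0.103), PTL by 3.68 (SE 0.137), PXL1 by 3.48 and PXY by 3.22 (SE 0.077, adjusted p = 3.1e-11). LBD1 and WOX14 had log2 fold changes of -3.43 and -3.19. PXY was 237.0 ± 9.94 CPM in mock and 25.38 ± 1.36 CPM in induced roots. PEAR1, RUL1, HAM4, CLE41, CLE44, SMXL4, TMO6, PXL2, CLE42 and SMXL5 had log2 fold changes between -2.64 and -1.09, and KNAT1, CYCD3;1, LBD11, ARF5, MOL1, HAM3 and PEAR2 between -0.94 and -0.34. PEAR2 was not called with total library size (adjusted p = 0.109, range 0.00555 to 0.109). SMXL3 rose by 2.03 on the log2 scale (SE 0.103), HAM1 by 1.66, MYB87 by 0.58 and HAM2 by 0.34.

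Suberin and cork genes showed a median of -4.32 at 24 h, with 22 of 23 lower and 1 higher, also adjusted over the list alone (adjusted p = 1.18e-21, and adjusted p = 0.104 with an estimated correlation). CYP86B1 fell by 5.45 (SE 0.197), ABCG2 by 5.09 (SE 0.172), ABCG20 by 4.89 (SE 0.164) and ABCG6 by 4.51 (SE 0.161), whereas MYB84, named after its values were seen, rose by 0.45 on the log2 scale. Of 28 xylem genes 27 fell, also adjusted over the list alone (median -1.92; adjusted p = 2.55e-06, and adjusted p = 0.436 with an estimated correlation). BFN1 fell by 2.55, FLA12 by 2.31, MYB83 by 2.06 and ACL5 by 0.93, and VND3 was not called. Of 17 phloem genes 14 fell and 1 rose, also adjusted over the list alone (median -1.67; adjusted p = 3.84e-07, and adjusted p = 0.212 with an estimated correlation). SULTR2;1 fell by 3.56, SEOR1 by 2.46 and CALS7 by 2.00, while SUC2, named after its values were seen, rose by 1.88 on the log2 scale to 139.1 ± 11.7 CPM. Of 15 lignin genes 12 fell and 2 rose, 13 and 2 adjusted over the list alone (median -0.89; adjusted p = 7.47e-05, and adjusted p = 0.212 with an estimated correlation). PAL4 fell by 3.78 and PAL1 by 2.75, while FAH1, named after its values were seen, rose by 2.08 on the log2 scale. PEP fell from 56.54 ± 3.38 to 0.3187 ± 0.159 CPM (log2 fold change -7.46, SE 0.254), CO2 fell by 5.30 and PHO1 by 2.86, while SKOR was not called. Cortex and pericycle counts were the same adjusted over the list alone. Endodermis genes had 7 of 9 lower and 1 higher, also adjusted over the list alone (median -1.83), and were not called as a list (adjusted p = 0.268), with SGN3 at -2.46 and SCR at 1.36.

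Cytokinin and auxin transport lists were called lower at 24 h and auxin biosynthesis higher. Of 28 cytokinin genes 22 fell and 3 rose, also adjusted over the list alone (median -2.86; adjusted p = 1.82e-07, and adjusted p = 0.0302 with an estimated correlation). ARR7 fell by 4.80 (SE 0.172), IPT3 by 3.40 and CKX6 by 2.99, and CKX7 rose by 1.50 on the log2 scale. Of 9 auxin biosynthesis genes 5 rose and 2 fell, also adjusted over the list alone (median 1.93; adjusted p = 0.0219, and adjusted p = 0.436 with an estimated correlation), and the call was lost with total library size (0.0529). YUC8 rose by 5.71 (SE 0.199, adjusted p = 2.05e-10) and TAA1 by 4.58 (SE 0.221) on the log2 scale. Of 14 auxin transport genes 9 fell and 3 rose, also adjusted over the list alone (median -1.16; adjusted p = 9.5e-05, and adjusted p = 0.19 with an estimated correlation), with PIN5 at -6.57, PIN7 at -2.81, LAX1 at -1.88 and AUX1 at -1.49. Auxin early response genes had 6 higher and 7 lower, also adjusted over the list alone, and were not called (adjusted p = 0.462); the test direction was up and the mean 0.31, against a median of -0.32. GH3.2 and LBD33 rose by 4.64 and 4.13 on the log2 scale and IAA3 fell by 1.89. Gibberellin genes had 11 of 14 lower and 1 higher, also adjusted over the list alone, and were not called (median -1.57, adjusted p = 0.138).

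S phase and mitosis lists were called higher at 24 h with the preset correlation, and D-type cyclin and CDK inhibitor genes were not called. Of 15 S phase genes 13 rose, also adjusted over the list alone (median 0.66; adjusted p = 0.000174, and adjusted p = 0.436 with an estimated correlation), with E2FA, TSO2 and CYCA3;2 at 1.72, 1.01 and 0.80. Of 23 mitosis genes 18 rose and 1 fell, also adjusted over the list alone (median 0.49; adjusted p = 0.00439, and adjusted p = 0.618 with an estimated correlation), with CYCB1;3 and CYCB1;4 at 1.09 and 0.59 and CYCA2;3 at -1.11. D-type cyclin and CDK inhibitor genes had 4 higher and 7 lower, also adjusted over the list alone (median -0.30, adjusted p = 0.401), with SIM at -4.09. Root tip genes had 3 of 4 higher, also adjusted over the list alone (median 2.19; adjusted p = 0.0275, and adjusted p = 0.183 with an estimated correlation), and the call was lost with total library size (0.0561). SHR (AT4G37650) rose from 13.55 ± 0.79 to 77.1 ± 9.79 CPM, WOX5 rose to 2.193 ± 0.353 CPM and SMB to 0.8133 ± 0.147 CPM.

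Of 19 clock genes 12 rose and 3 fell at 24 h, also adjusted over the list alone (median 0.57; adjusted p = 0.0464, and adjusted p = 0.52 with an estimated correlation). The clock call was lost without mock 24 h replicate 1 (0.0611), without induced 24 h replicate 3 (0.0523) and with total library size (0.0729). Cell wall loosening genes had 8 of 9 lower, also adjusted over the list alone (median -2.20; adjusted p = 2.64e-06, and adjusted p = 0.0828 with an estimated correlation), with EXPA6 at -1.82 and PME5 at -3.86. Lateral root and boundary genes had 6 higher and 3 lower, also adjusted over the list alone, and were not called (median 0.37, adjusted p = 0.0923), with CUC2 at 5.44 (SE 0.261) and WOX11 at 3.21. Photosynthesis genes had 9 of 11 lower, also adjusted over the list alone (median -0.47, adjusted p = 0.108), and were called with the replicate block that pairs libraries by number (0.0453) and without mock 24 h replicate 3 (0.0211). RBCS1B, which may share reads with its near copy RBCS3B, was at -4.53.

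The remaining lists were not called at 24 h. HD-ZIP III genes had 3 lower, also adjusted over the list alone (median -0.26, adjusted p = 0.319), with ATHB8 at -0.71. In the embryonic list 2 genes rose and 2 fell, also adjusted over the list alone (adjusted p = 0.952): AGL15 fell by 1.69, LEC2 had 68 counts in induced and 2 in mock roots, and ESR1 had 122 counts against 0, at least 36.7-fold higher. Jasmonate genes had 1 higher and 4 lower, 0 and 4 adjusted over the list alone (adjusted p = 0.831), with a median of 0.23 against a mean of -0.18 and a test direction of down, and VSP2 was at -2.81. Salicylate and defence genes had 2 higher and 2 lower, also adjusted over the list alone (adjusted p = 0.952), with a median of -0.01, or 0.13 with total library size, a mean of -0.47 and a test direction of up. Root hair genes had 3 higher, also adjusted over the list alone (adjusted p = 0.518), with a median of -0.43 against a mean of 0.29 and a test direction of up. Housekeeping genes had 3 higher and 3 lower, also adjusted over the list alone (adjusted p = 0.952), with a median of 0.15 against a mean of -0.03 and a test direction of down, and ACT2 was at -0.81.

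**Figure D3:**
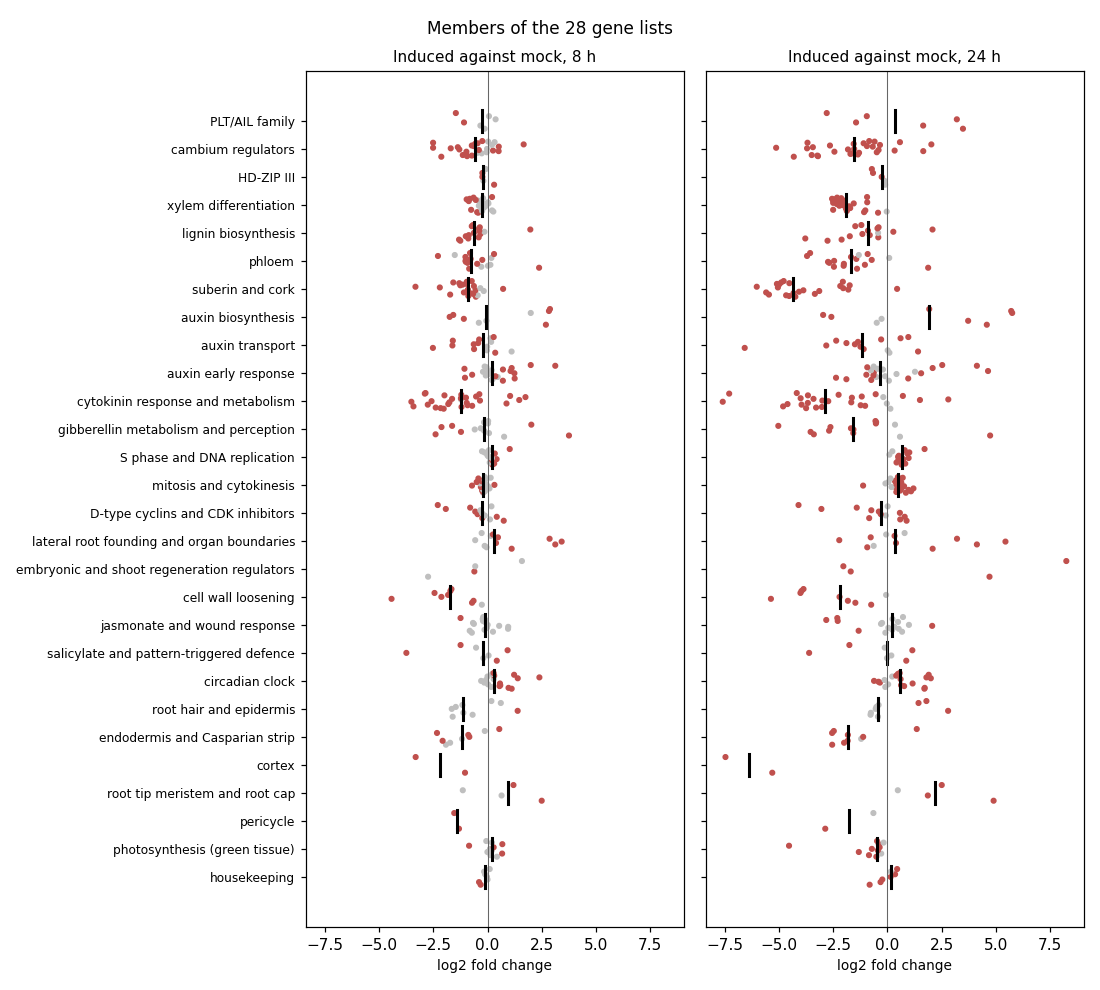
Log2 fold change of each tested member of the 28 lists at 8 h and 24 h, with red points for genes with an edgeR adjusted p under 0.05, grey points for the others and a black bar at the list median, left out for the embryonic list because LEC2 and ESR1 have a group at 0 counts. The suberin median moves from -0.90 to -4.32, the cytokinin median from -1.23 to -2.86 and the mitosis median from -0.20 to 0.49.

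The largest rises at 24 h were in genes with 0 to 2 counts over the mock libraries. AT4G19750, a chitinase-like gene next to its copy AT4G19730, had 2898 counts against 0, at least 873-fold higher, and AT4G19730 had 723 against 1 (ratio 691, counting interval 117 to 25900), with reads uncertain between them. The YABBY gene AFO had 895 counts against 1 (ratio 768, interval 145 to 32000), CYP81D2 had 783 against 1 (ratio 749, interval 127 to 28000) and the marneral synthase gene MRN1 had 1183 against 2 (ratio 548, interval 148 to 4420). Among the largest falls, CYP78A5 had 1 count in induced against 891 in mock roots (980-fold lower, interval 176 to 39000), AT1G20990 had 3 against 1503 and the peroxidase gene AT5G47000 had 2 against 1006. CYP78A8 fell by 9.11 (SE 0.268, adjusted p = 7.39e-11) and AT4G01390, encoding a TRAF-like protein, fell by 8.45 (SE 0.333, adjusted p = 4.84e-10).

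Responses at the 2 times overlapped. Genes that rose at both numbered 3885 against 1834 for independent lists, and genes that fell at both numbered 4339 against 1687. Of the 8 h calls 84.4% had the same direction at 24 h, 160 genes rose at 8 h and fell at 24 h, and 116 did the reverse. A further 7005 genes were called at 24 h and not at 8 h, and 1248 at 8 h and not at 24 h, which does not show that their responses differed. Log2 fold changes at the 2 times correlated with r = 0.78 and rho = 0.74 across genes. The times have separate mock libraries.

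The interaction tests which responses differed between 24 h and 8 h. Responses differed for 8740 genes, of which 3905 had a higher and 4835 a lower response at 24 h, and 2976 had an absolute difference of at least 1 (455 higher and 2521 lower). The share of higher differences was 44.7% with TMM, 41.7% with RLE factors and 51.5% with total library size. PXY had a difference of -2.50 (SE 0.101, adjusted p = 2.8e-08), ABCG2 of -4.12 (SE 0.215, adjusted p = 9.7e-08), PEP of -4.14 (SE 0.338, adjusted p = 1.87e-06) and YUC8 of 2.88 (SE 0.342, adjusted p = 4e-05). PLT1 and BBM had differences of 3.62 (SE 0.483, adjusted p = 9.79e-05) and 2.83 (SE 0.714, adjusted p = 0.00741), and the BBM call was lost without mock 8 h replicate 2 (0.0535), with a range of 0.000479 to 0.0535 over alternatives. ANT and PLT7 had differences of -1.33 and -1.01. The difference of PLT2 was not called (adjusted p = 0.0762), nor was that of PLT3. LBD4, TMO6 and WOX4 of the cambium list had differences of -2.00, -1.50 and -2.18, and HAM1 alone among its 29 members had a higher response called at 24 h, against 2 adjusted over the list alone.

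On the difference, 12 of 26 lists were called, 10 lower and 2 higher, of which only the cambium list (median -0.84, adjusted p = 8.95e-11) held with an estimated correlation (0.0489). With 23 of 29 members lower and 1 higher it was 23 and 2 adjusted over the list alone. Suberin genes had a median difference of -3.21 (20 of 23 lower, adjusted p = 1.58e-33, and adjusted p = 0.0731 with an estimated correlation), xylem genes -1.62 (26 of 28, 2.77e-09, and 0.353 with an estimated correlation) and phloem genes -1.2 (14 of 17, 15 adjusted over the list alone, 2.48e-08, and 0.21 with an estimated correlation). Cytokinin genes had -1.12 (19 lower and 1 higher, 4.79e-05, and 0.0731 with an estimated correlation), gibberellin genes -0.98 (8 lower, 10 adjusted over the list alone, 0.012, and 0.21), cell wall loosening genes -0.94 (6 lower and 1 higher, 0.00408, and 0.21), photosynthesis genes -0.94 (11 lower, 0.000583, and 0.412), auxin transport genes -0.61 (8 lower and 2 higher, 0.000502, and 0.21) and lignin genes -0.51 (8 lower and 1 higher, 0.0101, and 0.418). Mitosis genes had 0.61 (20 higher and 1 lower, 2.27e-08, and 0.353) and S phase genes 0.49 (12 higher, 13 adjusted over the list alone, 0.000109, and 0.418). Counts adjusted over the list alone were otherwise the same for these lists. Of the other lists, root tip genes had 3 of 4 higher (adjusted p = 0.0699), called without mock 8 h replicate 3 (0.0372) and without induced 8 h replicate 2 (0.0492). The 13 remaining tested lists had adjusted p-values from 0.197 for auxin biosynthesis to 0.957 for the PLT/AIL family, whose test direction was down against a median of 0.81 and a mean of 0.96. The tests of D-type cyclin genes (median 0.06, mean -0.19) and jasmonate genes (median 0.37, mean -0.04) also pointed down. So did that of the embryonic list (adjusted p = 0.924), although its fitted median and mean were above 0, which depend on LEC2 and ESR1 with a group at 0 counts.

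Among genes with at least 5 CPM in the highest group, the largest positive differences were in CYP81D2, MRN1, the bHLH gene AT4G37850 and the cold-regulated gene AT3G03341. Below that floor, the embryonic list held a difference of 7.45. CYP81D2 had 783 counts in induced 24 h roots and 0 to 1 in each other group, and MRN1 had 1183 against 26 in induced 8 h roots. AT4G37850 differed by 5.88 (SE 0.955, adjusted p = 0.00042) and AT3G03341 by 5.08 (SE 0.874, adjusted p = 0.000624). The calls of CYP81D2 and MRN1 (adjusted p = 0.0105 and 0.0152) were lost without mock 8 h replicate 3 (1 and 0.0873), and that of MRN1 also without mock 8 h replicate 1 (0.091). Over alternatives they ranged from 3.65e-06 to 1 for CYP81D2 and from 0.00117 to 0.091 for MRN1. Above the same floor, the largest negative differences were in the neighbours AT4G01390 and AT4G01380, in CYP78A5 and in AT2G48090. AT4G01390 differed by -7.77 (SE 0.404, adjusted p = 9.44e-08) and AT2G48090 by -6.28 (SE 0.42, adjusted p = 4.14e-07). AT4G01380 (adjusted p = 2.04e-06) had 602 counts in induced 8 h and 4 in induced 24 h roots. CYP78A5 (adjusted p = 4.61e-06) had 102 counts in induced 8 h and 1 in induced 24 h roots.

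The mock comparison asks what changed between 8 h and 24 h without induction. Of 23 mitosis genes 12 rose, in a list whose call was lost with an estimated correlation (adjusted p = 0.0779). GSTF7 fell from 78.91 ± 14.8 to 23.01 ± 5.55 CPM (log2 fold change -1.78, SE 0.17, adjusted p = 0.00415). In all, 142 genes changed, 105 higher and 37 lower, and 4 had an absolute log2 fold change of at least 1. This count was 385 with DESeq2, 1 without mock 8 h replicate 3 and 0 with edgeR on the 6 mock libraries alone, where 1691 genes had an unadjusted p under 0.05. CYP71B24, AT1G65970, AT2G29340 and AT2G33793 rose by 0.90, 0.81, 0.74 and 0.70 on the log2 scale, UGT74F2, AT4G25310 and AT4G02940 fell by 0.85, 0.81 and 0.80, and KNAT1 of the cambium list fell by 0.32 (adjusted p = 0.0435). The count of mitosis genes that rose was 22 adjusted over the list alone, and the list median was 0.45 (camera, adjusted p = 3.96e-49, and adjusted p = 0.0779 with an estimated correlation). Among them CYCB1;2, CYCB1;4, CDKB2;1 and KN rose by 0.46, 0.45, 0.56 and 0.35 on the log2 scale. S phase genes were called as a list (median 0.14; adjusted p = 1.65e-05, and 0.972 with an estimated correlation) with 0 members called by edgeR or DESeq2 and 5 at an unadjusted p under 0.05. Lignin genes were called lower (median -0.14; adjusted p = 0.0148, and 0.972 with an estimated correlation) with 0 members called by either tool and 2 at an unadjusted p under 0.05. The S phase call was lost without mock 8 h replicate 2 (0.0536) and the lignin call without mock 8 h replicate 2 (0.0641) or mock 24 h replicate 3 (0.0908). The other 23 lists had adjusted p-values from 0.4 to 0.904. Of these, the clock list was called without mock 24 h replicate 1 (0.0439), and cell wall loosening (0.0498) and photosynthesis (8.93e-05) without mock 24 h replicate 3. Of 19 clock genes 8 had an unadjusted p under 0.05, and 4 rose and 2 fell adjusted over the list alone. Adjusted in that way, 2 cell wall loosening genes and 1 auxin transport gene rose, and 1 gibberellin gene and 1 cambium gene fell. None of the 13 genes named for this comparison held in the fit of the 6 mock libraries, where CYCB1;2 had an adjusted p of 0.0595, and all but GSTF7 were lost without mock 8 h replicate 1 (KNAT1 0.136), mock 8 h replicate 3 (0.14), mock 24 h replicate 1 (0.145) or mock 24 h replicate 3 (0.176).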

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

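The tests of the PLT1, PLT2 and BBM pattern and of the suberin pattern were chosen after the results were seen, as were the list tests on the difference of the responses, whereas the gene-wise test of that difference and the splits of the libraries were planned. The results below stand out because the response to induction at 24 h differed from that at 8 h by the interaction test. In total 8740 genes differed, or 40.8% of those tested. Among 211 genes that the rule for named genes can name and that had a tested difference, 164 differed. Of these, 8 had changed in opposite directions at the 2 times. Many of the 211 entered through a call in these same data, some through the difference itself, so their share is not a test.

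The list medians of the difference (24 h minus 8 h) were -3.21 for suberin and cork, -1.62 for xylem, -1.2 for phloem, -1.12 for cytokinin, -0.98 for gibberellin, -0.94 for cell wall loosening, -0.94 for photosynthesis, -0.84 for cambium, -0.61 for auxin transport and -0.51 for lignin. They were 0.61 for mitosis and 0.49 for S phase, and of these 12 list calls only cambium held with an estimated correlation (adjusted p = 0.0489, against 0.0731 to 0.418 for the other 11). Among genes, the adjusted p of the difference was 0.0105 for CYP81D2, 0.00042 for AT4G37850, 0.0152 for MRN1 and 0.000624 for AT3G03341, which had larger responses at 24 h. CYP81D2 lost its call without mock 8 h replicate 3 (1), and MRN1 without mock 8 h replicate 1 (0.091) or 3 (0.0873). The adjusted p was 9.44e-08 for AT4G01390, 2.04e-06 for AT4G01380, 4.61e-06 for CYP78A5 and 4.14e-07 for AT2G48090, whose responses were lower at 24 h.

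The 8 genes with opposite responses included 5 that rose at 8 h and fell at 24 h: the cambium gene LBD11 (difference -1.19), TMO5 (-1.24), ACL5 (-1.14), and RBCS3B (-1.08) and RBCS1A (-0.64) of the photosynthesis list, with reads of RBCS3B uncertain against its copy RBCS1B. The 8 h rise of RBCS1A was not called without induced 8 h replicate 1 (0.0577) or 2 (0.064), with a range of 0.00257 to 0.064 over alternatives. The mitosis genes KN (0.61), CYCB1;2 (0.61) and CYCB1;4 (0.84) fell at 8 h and rose at 24 h, though the 8 h fall of CYCB1;4 was not called with total library size (0.0678, range 0.00264 to 0.0678).

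For the difference, 100 of the 200 possible exchanges of time labels within each treatment were drawn. Of these, 10 gave as many called genes, the real one with 8740 included and the highest other with 10508. Exchanges that moved only mock libraries kept the difference between induced libraries, so this count cannot exclude chance and does not argue for it. The criterion set in advance for excluding chance, which asked for fewer such exchanges, was not met. All 10 are among the 11 exchanges that kept the real induced libraries at their times (8308 to 10508 genes) and exchanged only mock libraries, in which 142 genes differed between the times. The highest count among the other 89 was 0. For induction at 8 h, 1 of the 10 splits of the 6 libraries gave as many genes (real 8842, highest other 0), and for 24 h 1 of 10 did (real 14716, highest other 0). Between the mock times 10 of 10 did (real 0, highest other 0). At 24 h, where libraries of the same number met the criterion for pairing, 4 splits part all 3 pairs, and the highest other count among these was 0. With 3 libraries against 3, the splits are too few for a share under 0.05. Each other split of an induction contrast also mixed mock and induced libraries in both groups, so the response itself widened the spread. Counts of 0 in such splits therefore say little about chance. The same holds for the 89 exchanges that mixed induced libraries of both times. Between the mock times every split gave 0, which cannot decide either.

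PLT1, BBM and PLT2 were higher at 24 h and not called at 8 h, and the difference was called for PLT1 and BBM but not for PLT2 (adjusted p = 0.0762). Reads of the induced PLT5 assigned to these genes would appear at 8 h too, since PLT5 had 88.2% of its 24 h gain by then, but the highest 8 h gain the libraries allow was 9.26% of the 24 h gain for PLT1 and 18% for BBM. For PLT2 that bound was 117% and the mean 8 h gain -12.5% of the 24 h gain, so its low counts alone cannot decide. Of 3691 words of 25 bases in PLT5, 0 were shared with PLT1, PLT2 or BBM. This argues against such reads for each of the 3 genes, though reads aligned with mismatches were not tested. For PLT1 and BBM together, a rise carried by 1 library is argued against by the summed CPM of the 3 genes, which exceeded every other library in 3 of 3 induced 24 h libraries (lowest 6.56 against 1.38). With 24 h gains of 3.64 and 2.13 CPM against 0.574 for PLT2, the sum does not speak for PLT2. The edgeR call of PLT2 at 24 h was lost without mock 24 h replicate 2 (adjusted p = 0.0709) or induced 24 h replicate 3 (0.057). Root tips in the induced segments may contribute, although segments were taken below the junction with the hypocotyl and visible lateral roots were removed, since 1 of 2 tested root cap genes, SMB, rose at 24 h with 102 counts in all against 25 in mock roots, and too few counts keep this open; a response to PLT5 also stays open.

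Suberin and cork genes were lower at 24 h with a median of -4.32. With total library size alone the median was -4.18, so the choice between these scalings does not account for the fall. That change of scaling moved all genes at 24 h by a median of only 0.142. Both scalings are relative, so a change in total RNA was not tested. For a loss of differentiated cells of every type alike, the lists moved apart. The strongest fall of a xylem gene was -2.55, while the cortex genes CO2 and PEP were at -5.30 and -7.46, below the suberin median. Expression of such genes in other cells would also make their falls unequal, so these values do not decide on such a loss. Fewer suberised cells in the segments cannot be told apart from lower expression within cells, since endodermis genes were lower too (median -1.83) while their list was not called and SCR rose. A response of suberin genes to PLT5 or to its effect on cell types could be either, and no other biological explanation was tested.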

How the results depend on the processing

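The list alternatives for the difference of the responses and for the mock times, and list tests with total library size, were chosen after seeing the data. An absolute log2 fold change of at least 1 left 2085 genes at 8 h, 5185 at 24 h, 2976 for the difference, 4 between mock times and 1845 shared by both inductions. Under the other alternatives the counts for 8 h, 24 h and the difference stayed within 1.5 times, and PLT5 kept its direction and call. The replicate block, which pairs libraries by number, gave 10360 genes at 8 h, 15893 at 24 h and 9379 for the difference. Correlations of paired deviations were 0.35, 0.09 and 0.11 at 8 h and 0.53, 0.20 and 0.08 between mock times, so only 24 h met the criterion for pairing.

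Genes called between mock times numbered 385 with DESeq2, 271 with the replicate block and 0 with edgeR on the 6 mock libraries (1691 at an unadjusted p under 0.05). The 6 libraries leave fewer samples to estimate spread, and for DESeq2 and the block the cause was not tested. Without single libraries this count ran from 1 (without mock 8 h replicate 3) to 150. Leaving out each library gave 7719 to 8922 genes at 8 h, 14604 to 15024 at 24 h and 7464 to 8534 for the difference.

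Lists called with an estimated correlation numbered 4 at 8 h, 2 at 24 h, 1 for the difference and 0 between mock times (1 at an unadjusted p under 0.05). With fry, which asks another question, they were 17, 21, 17 and 1 in the same order. Leaving out single libraries gave 11 to 12 lists at 8 h, 12 to 14 at 24 h, 12 to 13 for the difference and 1 (without mock 8 h replicate 2) to 4 between mock times.

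Of named genes called, 104 of 119 at 8 h, 138 of 142 at 24 h, 88 of 100 for the difference and 0 of 13 between mock times kept their call under each alternative run, as did 4 of 11, 2 of 13, 1 of 12 and 0 of 3 lists. No called result reversed. Transcript-length offsets and a test on normalized values were not run, as the files hold gene counts, and the 6-library fit has no difference of responses.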

Other observations

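The test of neighbouring genes was planned, and the gene families by product name were chosen after seeing the data. Neighbouring genes tended to change in the same direction at 24 h. Among 5185 genes called with an absolute log2 fold change of at least 1, 1149 neighbouring pairs shared a direction, against a mean of 803 and a highest of 879 in 1000 shuffles of gene order. Reads shared between neighbouring copies do not account for all of this, since pairs that share no word of 25 bases and do not overlap gave 927 against a mean of 662 and a highest of 738. Pairs that share words or overlap gave 222 against 141 and 178. Runs of lower genes included 8 genes from AT5G37970 to AT5G38030 on chromosome 5 (median log2 fold change -1.82). In it 0 adjacent pairs shared a word or overlapped. Another run held 8 genes from LPR1 to PIN7 on chromosome 1 (median -2.45), with 2 such pairs. Only adjacent genes were compared. The chromosome 5 run holds methyltransferase and dehydrogenase genes that alternate, so reads shared between copies further apart were not tested. Shared regulation of neighbours may contribute and was not tested.

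Of 124 families of at least 15 genes, camera called 20 at 8 h, 45 at 24 h, 47 for the difference and 4 between mock times. With an estimated correlation it called 0 in each, with 14, 22, 19 and 3 at an unadjusted p under 0.05. At 24 h, 36 of 47 pectin lyase-like genes fell and 1 rose (median -1.78, adjusted p = 3.49e-12, and adjusted p = 0.18 with an estimated correlation).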
